A study of Triticum aestivum with 8 samples.

How the data were processed

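RNA from leaves of bread wheat (Triticum aestivum) was measured on 8 Affymetrix arrays. Plants of the cultivars WL711 and C306 were either watered throughout or left without water from day 27 of age, and all samples were labelled as 48 days old. Each of the 4 combinations of cultivar and watering had 2 biological replicates. Per the labels' protocols, total RNA was extracted with the Spectrum Plant Total RNA Kit and biotinylated amplified RNA was prepared by the standard Affymetrix procedure.

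The deposited values are on a log2 scale: the submitters' processing notes name RMA, which fits 1 log2 value per probe set and array after quantile normalization, with the version not given in the sources used here. In the deposited table the median of every probe set over the 8 arrays was 0, with a largest absolute median of 5e-07, so the values were centred per probe set after RMA. Centring cancels in every difference between arrays, but it removes absolute signal. No statement about the level of a transcript was therefore made. Probe sets were set against each other only in how they differed between arrays. Scanner values were not used here, so the log base and the direction rest on the processing notes and were not set against raw intensities. The medians of the 8 arrays were 0.024 and 0.023 for WL711 control, 0.011 and 0.018 for WL711 drought, -0.0058 and -0.012 for C306 control, and -0.025 and -0.019 for C306 drought (log2, replicates 1 and 2). The number of arrays limits the precision of every value below.

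The table held 61290 probe sets. The 111 Affymetrix control probe sets were left out of the tests, and 61179 remained. The platform annotation paired 1273 probe sets with 1 gene each, none with several, and gave no gene for 59906. Those 1273 probe sets stood for 771 genes, of which 770 were found by gene number in the gene table of the IWGSC CS RefSeq v2.1 assembly, used here for names only. A name other than LOC with digits, counting synonyms in that table, was found for 102 genes with 200 probe sets. Probe sets outside this annotation are described by their rank in a comparison.

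The main test was limma 3.58.1 in R 4.3.3, with lmFit over all 8 arrays and 4 group means, contrasts.fit, and eBayes without a trend. The fit had 4 residual degrees of freedom and 4.63 prior degrees of freedom. A probe set passed with a Benjamini-Hochberg adjusted p under 0.05 over the 61179 probe sets. There were 5 comparisons: drought against control in each cultivar, the difference of these effects, and C306 against WL711 under each watering. SE is the moderated standard error from limma, and SD is taken over the 2 arrays of a group. On simulated data for the WL711 drought comparison, with 61179 probe sets and 200 changed ones in each of 10 runs, the test recovered 28.4% of log2 changes of 1, 94% of changes of 2, 99.4% of changes of 3 and 100% of changes of 4, and 5.74% of its calls were false. These simulations drew equal array quality in every group. In the data, 10 of 101 probe sets with an absolute log2 change of at least 2 passed in WL711, and 22 of 230 in C306. The simulated recovery therefore does not show that the drought lists are complete.

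Of 23 gene lists fixed as text patterns before the data were examined, 12 matched at least 1 named gene and 11 matched none. Lists with at least 5 genes were tested with camera in limma at a preset correlation of 0.01, over 1 probe set for each of 771 genes. Only 1 fixed list, of tubulins and histones, was large enough, and its patterns missed wcH2B-6 and wcH2B-8. Another 7 lists were put together after values had been seen, and 4 of these were tested. In simulations, camera found 40 of 40 lists of 6 genes shifted by 1 and called 1 of 40 random lists.

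The rule for named genes was also fixed before the data were examined. In each drought comparison it took the 8 highest and 8 lowest named genes past the threshold whose drought arrays both lay beyond both control arrays, plus 2 per list. In the other comparisons it took the 6 highest and 6 lowest past the threshold. Where none passed, it took the 4 highest and 4 lowest by moderated t. It left the choice among several probe sets of a gene to the highest mean value, which has no meaning on centred values. In its place, a plain _at probe set stood for its gene, then _a_at, _s_at and _x_at, then identifier order. Probe sets without a gene, LOC genes, PR5, the dehydrin genes, TaGlu1a, tubb1, H2A-9 and 6-FEH were singled out after their values were seen.

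Alternatives were a block for the replicate number, arrays shifted to one median, quantile normalization once more, a minimum absolute log2 change of 1, eBayes with trend and robust, array weights, removal of probe sets ending in _x_at, _s_at or _a_at, each array left out in turn, and a fit on the 4 arrays compared. The planned removal of probe sets with a mean log2 value under 5 was not run, because centred means do not measure brightness. The trend in eBayes was likewise fitted on centred means and not on brightness. Quantile normalization once more acted on centred values, so it did not repeat the step in RMA. Hybridisation controls, which are added to the labelled RNA, were low on 3 arrays, so these arrays were entered as a block, an alternative chosen after seeing the data, as were separate fits for each watering. Those arrays came from 3 groups, 1 from each, so no comparison could be made within them. No probe coordinates were used.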

Results

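Leaf transcripts were compared between watered and droughted plants of WL711 and C306. C306 is known among breeders as a drought-tolerant wheat and WL711 as a drought-susceptible one. The droughted plants had gone 21 days without water at the labelled age of 48 days. Each group held 2 arrays. Cultivar separated the arrays most: the first principal component carried 57.5% of the variance and placed all WL711 arrays on one side and all C306 arrays on the other. The next components carried 12.7% and 11.4%. The interquartile range of the centred values was 0.482 on WL711 control replicate 1 and 0.221 to 0.302 on the other 7 arrays. Mean signal of the hybridisation controls was -0.72 on WL711 control replicate 1, -0.98 on C306 control replicate 2 and -0.91 on C306 drought replicate 1, and 0.022 to 0.13 on the other 5. The poly-A controls, another kind of Affymetrix control probe set, averaged 0.59 and 0.52 on C306 control and -0.053 and -0.042 on C306 drought. On WL711 control they averaged -0.71 and -0.14, and on WL711 drought 0.24 and -0.39 (replicates 1 and 2). They parted C306 control from C306 drought and from WL711 control. A technical difference in those comparisons was not separated from watering or cultivar. Actin control probe sets were read as 3' minus 5' centred signal, which compares arrays and gives no 3' to 5' ratio. The actin probe sets stood at 0.42 and 0.27 on WL711 control and -0.35 and -0.022 on WL711 drought (replicates 1 and 2). On C306 control they stood at -0.11 and 0.26, and on C306 drought at -0.24 and -0.083. Those of GAPDH did not part the groups, at -0.091 and 0.029 on WL711 control, -0.047 and -0.11 on WL711 drought, 0.20 and -0.055 on C306 control, and 0.10 and -0.058 on C306 drought.

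The first question was which leaf transcripts changed in WL711 when water was withheld. LOC543440 rose from -1.45 ± 0.15 to 0.0046 ± 0.15 (centred log2, SD, n = 2), a log2 change of 1.45 (SE 0.17, limma adjusted p = 0.0444). It was the only probe set with a gene in the annotation to pass. Among probe sets without a gene that passed, the one with the largest decrease fell by 5.06 on the log2 scale (SE 0.25, limma adjusted p = 0.000982). The next fell by 3.52 (SE 0.31, adjusted p = 0.0271). The largest increases that passed were 3.73 (SE 0.39, adjusted p = 0.0394) and 2.84 (SE 0.24, adjusted p = 0.0271). In all, 22 of 61179 probe sets passed, 10 higher and 12 lower, and 8413 had an unadjusted p under 0.05.

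None of the 102 named genes passed in WL711, whether adjusted over all probe sets or over the named genes alone, and 17 had an unadjusted p under 0.05. The named genes with the highest moderated t, none past the threshold, were FKBP70, a peptidyl-prolyl isomerase, at a log2 change of 0.60, the zinc finger gene WZF1 at 0.95, SAHH, which encodes S-adenosylhomocysteine hydrolase, at 0.92, and the ribosomal protein gene RPL9 at 1.08. The lowest were the gibberellin 20-oxidase genes Ta20ox1D at -0.69 and Ta20ox1B at -0.62, the alpha-amylase inhibitor gene WMAI-1 at -0.59, and TaPMM, which encodes phosphomannomutase, at -0.57. Adjusted p for these 8 genes ran from 0.179 to 0.270 (limma).

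The few named genes of kinds commonly induced by water deficit did not pass in WL711. Lists covered named genes only, so genes and probe sets without a name were not screened for such functions. The 3 members of the dehydrin and LEA list were COR410 at -0.30 (SE 0.16), Rab15 at -0.17 (SE 0.28) and LEA1 at 0.41 (SE 0.22), and 0 passed when adjusted over the list alone. The photosystem genes PsbO and PsbP stood at 0.026 and 0.065, the Rubisco gene rbcl at -0.22 (-0.98 to 0.36 over its 28 probe sets), and the heat shock gene hsp16.9A at 0.059. CAT1 and GSTZ1, which act in detoxification, stood at 0.12 and 0.080, XTH of cell wall loosening at -0.083, and the 3 serpins of the seed storage list between -0.29 and -0.17. For the ribosomal proteins RPL9 and RPS29, at 1.08 and 0.75, 1 of 2 passed when adjusted over the list alone. PR5, a thaumatin-like defence gene, read 2.18 (SE 1.42), with 4.59 on drought replicate 1 and -1.06 on replicate 2, and -0.64 without drought replicate 1. The tubulin and histone list was not shown to shift (camera adjusted p = 0.924), but lay above the other genes when every probe set was counted (adjusted p = 0.0242). Its mean was 0.082 and its median 0.11, above 0, while the test placed it below the other genes.

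A single array decided how many WL711 probe sets passed: 0 without control replicate 1, 49 without control replicate 2, 14 without drought replicate 1 and 2 without drought replicate 2. With the replicate number as a block, 81 passed, 54 higher and 27 lower, with the 3 arrays of low hybridisation controls as a block, 4 passed, all lower, and the call for LOC543440 was lost in 13 of 17 alternatives (adjusted p 0.0392 to 0.212).

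The same question was asked in C306. LOC543233 rose from 0.0089 ± 1.16 to 5.71 ± 0.83 (SD, n = 2), a log2 change of 5.70 (SE 0.57, limma adjusted p = 0.0191), while the other probe set of LOC543233 read 5.53 (SE 0.77, adjusted p = 0.0841). LOC543248 rose from -2.77 ± 0.04 to 0.35 ± 0.19, a log2 change of 3.12 (SE 0.17, adjusted p = 0.000848). The probe set with the smallest adjusted p, without a gene, rose by 3.88 (SE 0.18, adjusted p = 0.000441). Of the probe sets past the threshold, those with the largest decreases had no gene. One fell by 3.63 (adjusted p = 0.00934) and another fell by 2.51 (adjusted p = 0.00251). In all, 30 probe sets passed, 24 higher and 6 lower, and 4727 had an unadjusted p under 0.05. Of these 30, 9 changed by at least 4 on the log2 scale, against 1 of 22 in WL711, while over all 61179 probe sets the median absolute change was 0.128 in C306 and 0.188 in WL711. After quantile normalization once more, the split was 16 higher and 11 lower in C306, and 4 higher and 12 lower in WL711.

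No named gene passed in C306, and 7 of 102 had an unadjusted p under 0.05 (limma). The highest by moderated t, none past the threshold, were APT1, for adenine phosphoribosyltransferase, at 0.55, DMAS1, for the phytosiderophore enzyme deoxymugineic acid synthase, at 0.90, cys1 at 0.61, and the phytochelatin synthase gene TaPCS1 at 0.36. The lowest were the dehydrogenase gene GAPN at -0.48, the beta-tubulin gene tubb2 at -1.42, the peroxidase gene TaPrx1 at -0.50, and the phosphoglycerate kinase gene Pgk-1 at -0.39. Adjusted p for these 8 genes ran from 0.301 to 0.704.

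Tubulin and histone genes lay lower as a group in C306 under drought. Of 9 members, 8 were below 0, among them all 6 tubulins, and the list mean was -0.43. By its wording the list left out the histone genes wcH2B-6 and wcH2B-8, at -0.33 and 0.088. None of the 9 passed alone, also when adjusted over the list alone. The list shifted down against the other annotated genes (camera p = 0.0111, the only fixed list tested), but p = 0.0891 with an estimated correlation. When the 4 lists chosen after seeing the data were counted, adjusted p was 0.0553, and 0.446 with an estimated correlation. By representative probe sets the lowest members were tubb2 at -1.42 (SE 0.55) and tubb1 at -0.80 (SE 0.44). Under the alternatives tubb2 read -1.97 to -0.88 and tubb1 -1.30 to -0.31. The histone gene H2A-9 stood at -0.46 (SE 0.25), and its 5 other probe sets between -1.11 and -0.40.

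The same named water-deficit and photosynthesis genes did not pass in C306 either. COR410 stood at 0.070 (SE 0.16), Rab15 at -0.31 (SE 0.28) and LEA1 at 0.038 (SE 0.22). PsbO and PsbP stood at -0.021 and -0.16, and rbcl at 0.14 (-0.70 to 0.26 over its 28 probe sets). The others were hsp16.9A at -0.16, CAT1 at 0.17, GSTZ1 at 0.046, XTH at -0.45, RPL9 at -0.47 and RPS29 at -0.39. The serpins lay between -0.23 and 0.038. PR5 read 2.53 (SE 1.42, adjusted p = 0.810), with both drought arrays above both control arrays. The beta-glucosidase gene TaGlu1a, which the flowering list took in by its wording, stood at 1.16 (SE 0.71, 0.11 to 2.22 under the alternatives). GBSS-I, which the wax list took in the same way, stood at -0.15. In each of these lists 0 members passed when adjusted over the list alone.

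The C306 count rose to 421 without C306 control replicate 2, 269 higher and 152 lower, and all 30 probe sets were among them. It was 72 without C306 drought replicate 2, 16 without C306 control replicate 1, 9 without either WL711 control array and 12 without either WL711 drought array, 3 in a fit on the 4 C306 arrays, and 0 with eBayes trend and robust. The call for LOC543233 was lost in 8 of 16 alternatives (adjusted p 0.000278 to 0.382) and the call for LOC543248 in 1 of 16.

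**Figure D1:**
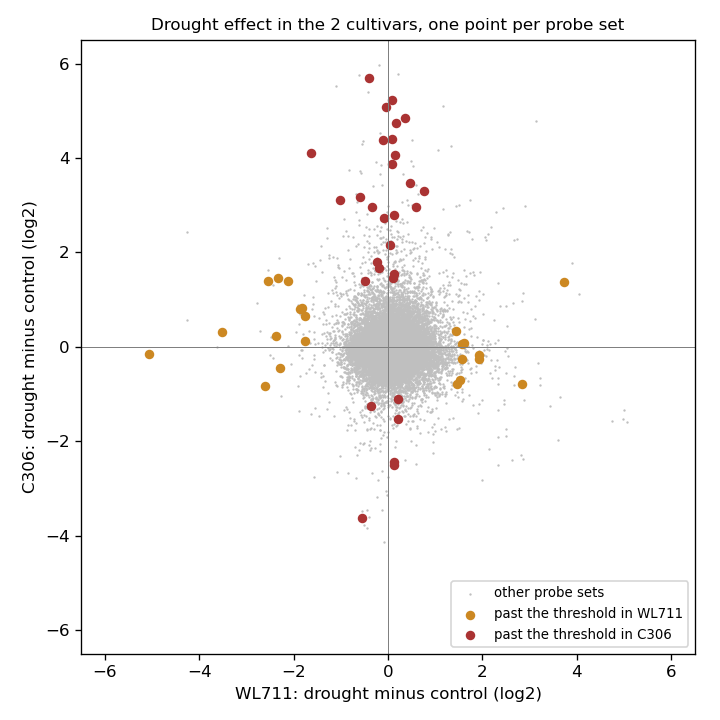
Log2 change under drought in WL711 (horizontal axis) against C306 (vertical axis), each the difference of 2-array means, one point per probe set over 61179 probe sets. The 22 probe sets past the threshold in WL711 spread along the horizontal axis and the 30 in C306 along the vertical axis, and none is shared.

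Drought effects were then set against each other to ask whether the cultivars responded alike. Of the probe sets past the threshold, that of LOC543150 had the largest difference. Its log2 change was -4.27 in WL711 and 2.43 in C306, a difference of 6.70 (SE 0.80, limma adjusted p = 0.0485). The other probe set of LOC543150 read -0.68 and 2.13, a difference of 2.81 (SE 0.46) that did not pass (adjusted p = 0.107). For LOC543248 the changes were -1.02 and 3.12, a difference of 4.14 (SE 0.24, adjusted p = 0.00170). For LOC543440 they were 1.45 and -0.78, a difference of -2.23 (SE 0.24, adjusted p = 0.0287). In all, the effect differed for 25 probe sets, 19 with a higher change in C306 and 6 with a lower one, and 5987 had an unadjusted p under 0.05. Of these 25, 11 passed in WL711, 10 in C306 and none in both, and the estimates had opposite signs for 21. Selection for a large difference by itself favours opposite signs.

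No named gene passed the test of the difference, with 12 of 102 at an unadjusted p under 0.05 (limma). Those with the highest moderated t were TaPMM at 0.77, APT1 at 0.53, cys1 at 0.94 and TaPCS1 at 0.58. The lowest were WZF1 at -1.23, RPL9 at -1.56, FKBP70 at -0.67 and Glc1 at -0.78. Adjusted p for these 8 ran from 0.307 to 0.481. The tubulin and histone list was not shown to differ between cultivars (camera adjusted p = 0.340 over 5 lists).

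No probe set passed in the same direction in both cultivars. Independent lists of those sizes would share 0.00392 higher and 0.00118 lower ones, so 0 shared calls is what such short lists give. Across all 61179 probe sets, which are not independent of each other, Pearson's r of the drought effects was 0.0266 and Spearman's rho 0.0552. Of the 24 probe sets higher in droughted C306, 13 were also above 0 in WL711, and of the 10 higher in droughted WL711, 4 were above 0 in C306. Of the 12 lower in droughted WL711, 3 were below 0 in C306, and of the 6 lower in droughted C306, 2 were below 0 in WL711. The count of differing probe sets was 2 without WL711 control replicate 1, 15 without control replicate 2, 9 and 4 without WL711 drought replicates 1 and 2, 199 without C306 control replicate 2 and 46 without C306 drought replicate 2, and the call was lost in 8 of 16 alternatives for LOC543150 and in 10 of 16 for LOC543440.

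Under control watering the question was which transcripts differ between the cultivars. The gene WZF1, for a zinc finger protein, was higher in C306 by 4.03 (log2, SE 0.26, limma adjusted p = 4.24e-05), with centred means of 1.74 ± 0.39 in C306 and -2.29 ± 0.48 in WL711 (SD, n = 2). XIP-I, a xylanase inhibitor of plant defence, was higher by 2.01 (SE 0.31, adjusted p = 0.00554), and its other probe set by 2.07. The fructan exohydrolase gene 1-FEH was higher by 1.04 (SE 0.16, adjusted p = 0.00564). RPS29 was higher by 2.99 (SE 0.47, adjusted p = 0.00586), although its other probe set read 0.36. Of the related gene 6-FEH, 2 of 3 probe sets were higher and the representative one read -0.29.

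Named genes lower in C306 under control watering included lgul, for lactoylglutathione lyase, at -1.39 (SE 0.29), TaPrx1 at -0.88 (1 of 4 probe sets passed, up to -0.32), the histone gene wcH2B-8 at -0.86 (2 of 7 passed, up to 0.078), the gibberellin 20-oxidase gene Ta20ox1D at -0.79 (1 of 2 passed, the other at -0.55), ATI (LOC543286), listed under a name for amylase/trypsin inhibitors, at -0.75 (1 of 3 passed, up to -0.33), and Pgk-1 at -0.74. Their adjusted p ran from 0.0173 to 0.0260 (limma), apart from ATI (LOC543286) at 0.04999. In all, 11 of 102 named genes passed, 4 higher and 7 lower, and 10 passed when adjusted over the named genes alone. By list, RPS29 of the ribosomal proteins passed and RPL9 read 0.056. By representative probe sets, no member of the lists of dehydrins and LEA proteins, photosystem proteins, serpins, or tubulins and histones (without wcH2B-6 and wcH2B-8) passed, while the other probe set of PsbP read -0.73 (adjusted p = 0.0445). For rbcl, 5 of 28 probe sets passed as lower in C306, down to -1.61, while its probe sets ranged up to 0.48. GSTZ1 read 0.57 and passed only when adjusted over the list alone.

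Over the whole array, 6714 probe sets (10.97%) differed under control watering, 4080 higher and 2634 lower in C306, of which 2971 differed by at least 1. The most extreme, a probe set without a gene, was higher in C306 by 8.61 (SE 0.16). LOC780634 was lower in C306 on all 3 of its probe sets, from -7.68 to -6.88. LOC100037541 read -7.78 (SE 0.53) on one probe set and -0.47 (SE 0.26) on its other. WZF1, XIP-I, 1-FEH, LOC780634 and LOC100037541 passed under all 17 alternatives, and RPS29 under all 16 that held its probe set. ATI (LOC543286) was lost in 15 of 17, and the others named here in 4 to 6. Counts fell to 2854 without WL711 control replicate 1, 3096 without C306 control replicate 1 and 3445 without C306 control replicate 2.

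**Figure D2:**
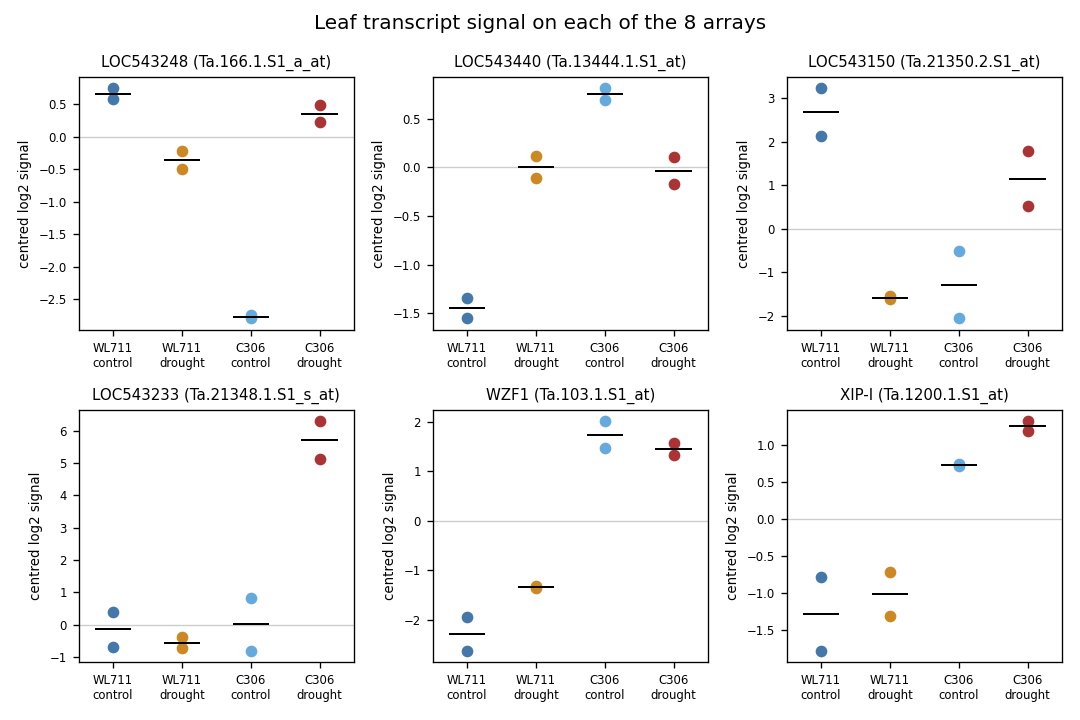
Centred log2 signal (vertical axes) on each of the 8 arrays for 6 genes, by cultivar and watering. Points are single arrays and black bars are means of 2 arrays. LOC543233 stands at 5.71 in droughted C306 alone, and WZF1 and XIP-I separate the cultivars under both waterings. Estimates for LOC543248 and LOC543440 differ from control in opposite directions in the cultivars. The change passed only in C306 for LOC543248 and only in WL711 for LOC543440.

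Under drought the cultivars were compared again, on the other 4 arrays. WZF1 was higher in C306 by 2.80 (SE 0.26, limma adjusted p = 0.000360), XIP-I by 2.26 (SE 0.31, adjusted p = 0.00328) and 1-FEH by 0.75 (SE 0.16, adjusted p = 0.0285). Lower in C306 were lgul at -2.05 (SE 0.29, adjusted p = 0.00416), RPL9 at -1.50 (SE 0.34, adjusted p = 0.0346), TaPrx1 at -1.02 (3 of 4 probe sets passed), Pgk-1 at -0.87 and GAPN at -0.74. LOC780634 read -8.27 to -6.84 over its 3 probe sets. Of 102 named genes, 8 passed, 3 higher and 5 lower, and 11 passed when adjusted over the named genes alone. By list, RPL9 passed and RPS29 read 1.85 (adjusted p = 0.0519). For rbcl, 1 of 28 probe sets passed, at -1.26. GSTZ1 at 0.54 and XTH at -0.62 passed only when adjusted over their lists alone, and TaGlu1a at 2.65 when adjusted over its list or over the named genes alone.

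In all, 4120 probe sets differed between cultivars under drought, 2570 higher and 1550 lower in C306. Of the 4080 higher under control watering, 1504 were higher here too, where independent lists would share 171.4, and of the 2634 lower, 846 were lower here, against 66.7. Both comparisons take their SE from the one fit over 8 arrays, so their calls are not independent. In separate fits for each watering, chosen after seeing the data, 1142 were shared higher against 96.3 and 558 lower against 28.4. Across probe sets, Pearson's r of the cultivar differences was 0.686 and Spearman's rho 0.526, and 23 probe sets passed in opposite directions. The drought count was 1892 and 1784 without WL711 drought replicates 1 and 2, 1626 and 2505 without C306 drought replicates 1 and 2, and 2475 with the low hybridisation controls as a block. Calls for WZF1, XIP-I and lgul held under all 17 alternatives, while 1-FEH and GAPN were lost in 7, Pgk-1 in 5, RPL9 in 4 and TaPrx1 in 3.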

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

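The tests of whole-cultivar label exchange and of drought RNA in a control sample were chosen after the result they bear on was seen, as were the block for low hybridisation controls and separate fits for each watering.

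Drought effects differed between WL711 and C306 by the test of the difference itself for 25 probe sets. Those with a gene in the annotation were LOC543150 (C306 change minus WL711 change 6.70, and 2.81 on its other probe set, which did not pass), LOC543248 (4.14) and LOC543440 (-2.23). For LOC543248 the C306 control arrays read -2.80 and -2.74 and the other 6 arrays -0.50 to 0.74, and the call held in 14 of 15 alternatives. LOC543150 held in 8 of 16 and LOC543440 in 6 of 16. Among those of the 25 probe sets without a gene, the highest differences were 5.74 and 4.91 and the lowest -3.63 and -2.63.

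The drought effects of the cultivars hardly correlated over probe sets, with r = 0.0266. An exchange of 1 control with 1 drought array is argued against: other splits of a cultivar's 4 arrays called at most 4 probe sets, against 22 and 30 for the labelled splits. Effects from array pairs that share no array correlated at 0.367 in C306 and at 0.271 in WL711. The latter fell short of the 0.3 set beforehand for ruling noise out. The 16 such pairings between cultivars ranged from -0.20 to 0.26 with a mean of 0.0151. A fully shared effect would correlate between cultivars about as strongly as within them. Labels exchanged for a whole cultivar would make that correlation negative. No pairing between cultivars reached 0.271 in size, and their mean of 0.0151 lay well below it. This comparison was not among those set beforehand, the pairings share arrays, and the highest came near 0.271. It therefore does not exclude noise hiding a shared or turned effect, or labels exchanged for a whole cultivar. A partly shared effect under noise stays open too. A cultivar-specific response, which the design names, may underlie the pattern but was not told apart from these.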

How the results depend on the processing

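Counts in the drought comparisons moved by over 1.5 times under several choices, and the cause was not tested, while a minimum change of 1, a shift to one median and quantile normalization moved none of them that far. The WL711 count of 22 became 5 with eBayes trend and robust, 1 with array weights and 4 with low hybridisation controls as a block (chosen after seeing the data). Array weights were equal within each group, so they weighted groups and not single arrays. They were 0.569 for WL711 control, 1.17 for WL711 drought, 0.990 for C306 control and 1.52 for C306 drought. The C306 count of 30 became 0 with trend and robust (4727 had an unadjusted p under 0.05 in the reported fit), 65 with array weights and 3 on its 4 arrays alone. The trend followed centred means, which do not measure brightness. Counts with trend and robust therefore do not show what a trend on signal would give. Without _x_at, _s_at and _a_at probe sets, with fewer tested, it was 16 and the count of differing effects 14 against 25. With a minimum change of 1, the cultivar counts of 6714 and 4120 became 2971 and 2604, with array weights 3516 and 7019. The first was 2965 on its 4 arrays and the second 2475 with the block for low hybridisation controls. Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated from -0.093 to 0.112. With the replicate number as a block, 81 probe sets passed in WL711, 54 higher and 27 lower, and no other count moved by over 1.5 times. Leaving out each array gave 0 to 49 in WL711, 9 to 421 in C306, 2 to 199 for the difference, 2854 to 9509 and 1626 to 4433 for the cultivar comparisons, and 0 to 1 shared drought calls. In these fits the lone array of a group is assumed to vary like the others. Of the 2 list tests, 1 passed as reported, 0 with an estimated correlation, with fry and when adjusted over 5 lists, and 2 with every probe set. For tubulins and histones in C306 p was 0.0891 with an estimated correlation, 0.0556 with fry, 0.182 with fry mixed, 0.0553 over 5 lists, and 0.00563 to 0.0430 with each array left out. In WL711 fry, which sets a list against no change and not against other genes, placed them upward with a p of 0.676, and camera did with every probe set (0.0242), the probe set with the highest mean (0.910), without WL711 control replicate 2 (0.398) and without either C306 drought array (0.946), and leave-one-out p ran from 0.253 to 0.946. Signs turned for PR5 in WL711 (-0.64 without drought replicate 1, up to 5.01), Rab15 in WL711 (0.29 without drought replicate 2), and COR410 and LEA1 in C306 without control replicate 1 (-0.069 and -0.17, up to 0.21 and 0.25 with each array left out), LEA1 also without drought replicate 1 (-0.032). The photosynthesis and Em lists, chosen after seeing the data, turned upward in C306 without control replicate 2 (both 0.984, from 0.251 and 0.103 with each array left out), the first also without drought replicate 1 (0.792) and the second with the highest mean (0.876). Of 1301 values of single genes and probe sets under alternatives, 1145 kept direction and side, 150 lost a call, 1 gained one and 5 turned. The 1301 include values of results that had not passed as reported and so could not lose a call. The share kept therefore does not measure how stable the calls are. The dim filter was not run, and signal over background is unknown on centred values.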

Other observations

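The test of the low hybridisation controls and the test on other probe sets of a gene were planned before their results were seen. The test of drought RNA in a control sample was not.

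Without C306 control replicate 2, 421 probe sets passed in droughted C306, among them genes that the full comparison left short of the threshold. That fit leaves 1 C306 control array, so the spread between the controls is not measured in it. LOC543234 read 7.57 higher, LOC543313 6.27 higher and LOC543363 5.59 higher. Their C306 control replicates 1 and 2 lay far apart, at -0.31 and 4.02, -0.37 and 3.09, and 0.16 and 2.64. All 3 probe sets of LOC780599 were lower, by -4.88 to -4.26. The only named gene to pass there by its representative probe set was DMAS1, which makes an iron-chelating phytosiderophore, at 1.35. With all arrays the same genes read 5.40, 4.54, 4.35 and, for DMAS1, 0.90. Leaving out the other control array instead gave 16 calls, and 13 were called in both cases.

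Gene groups put together after seeing the data add 2 values in WL711. A list of 18 seed storage proteins and inhibitors, such as gliadins, avenin-like proteins, serpins and thionins, lay lower under drought (mean log2 change -0.17, camera adjusted p = 0.0242), with adjusted p = 0.364 with an estimated correlation, both over 5 lists. None of the 18 passed alone. Centred values do not show whether these seed genes gave signal above background in leaves, so a leaf response is not established. The list also lay lower in watered C306 than in watered WL711 (mean -0.25, adjusted p = 0.0253, and 0.594 with an estimated correlation), a comparison that shares the WL711 control arrays, and under drought its mean was -0.16 (adjusted p = 0.232). A list of 7 translation genes, among them RPL9, TEF1 and eIF4E, had a mean of 0.41 (camera adjusted p = 0.0546, and 0.364 with an estimated correlation). The mean for 6 photosynthesis genes was -0.035 and for 5 genes of the Em and LEA type -0.052. Gibberellin 20-oxidase genes averaged -0.39 and the raftin genes of anthers -0.28. Fructan exohydrolase genes averaged 0.075 by representative probe sets, of which that of 6-FEH read -0.29, while its other 2 read 1.93 and 2.20 (none passed).

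Of 85 probe sets at least 3 higher on both C306 drought arrays than on control replicate 1, replicate 2 lay a median 59.2% of the way to drought, while of 16 chosen the same way against replicate 2, replicate 1 lay at -17.7%. Selection on a low control array can by itself place the other control towards drought, although it did not for those 16. In WL711 the same selections gave 43.8% (22 probe sets) and 39.99% (11, with quartiles -78.1% and 75.5%). A middle position is therefore not particular to this array, while the contrast between the 2 C306 controls had no like in the WL711 medians. Drought RNA mixed into the sample would give 1 linear share for every transcript, and stays open: 44.7% of the 85 lay within a factor of 2 of the median share (95% interval 33.9% to 55.9%), and the selection shaped these shares. A shift common to the arrays with low hybridisation controls stays open too: over the same probe sets WL711 control replicate 1 exceeded replicate 2 by a median 1.17, against 2.61 for C306 control replicates 2 and 1, while C306 drought replicate 1 exceeded replicate 2 by 0.030. Differences between plants of one group, such as in water status, may also be the source and were not tested.

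Cultivar differences on arrays could come from sequence differences under the probes of 1 probe set, or from transcript amount or gene content. Among 22 genes with a probe set that differed by at least 1 under both waterings and with at least 1 other probe set, the others shifted in the same direction by a median 0.77 (quartiles 0.29 and 1.53), against a median 2.19 for the strongest. That lies between the bounds of 0.25 and 1 set beforehand, so the explanations cannot be told apart for these genes as a set. The others shifted in the same direction for 18 of 22 genes and by at least 1 for 9, among them XIP-I, lgul and LOC780634, and by under 0.25 for 5. Probe sets whose identifiers differ only in the ending, such as those of XIP-I, may share target sequence. Agreement between such probe sets does not separate the explanations. LOC100037541 read -7.97 on one probe set (mean of both waterings) and 0.38 in that direction on its other.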
